A study of Arabidopsis thaliana with 9 samples.

How the data were processed

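Gene expression was measured by sequencing of polyadenylated RNA from whole Arabidopsis seedlings in 9 libraries, 1 for each combination of 3 genotypes and 3 treatments. Per the labels' protocols, mRNA was taken with oligo-dT, primed at random and amplified in 18 cycles of PCR without molecular identifiers, and RNA of 3 experiments was pooled before each library was made. Intervals and floors therefore cover counting error only. The submitters' processing notes name CASAVA 1.6 and TAIR10 with no role. The aligner, the counting program and the use of strand were not given in the sources used here.

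Each library has 1 table of 33518 genes. Per the file headers it holds the gene length, the estimated count of reads, the RPKM and the fraction of the gene's reads that map to several places. The deposited estimated counts apportion multi-mapping reads between genes, so that between 92.3% and 95.4% of all values, zeros included, and between 88.9% and 92.6% of the values above 0 were whole numbers within 1e-06. The deposited RPKM are reads scaled by gene length and by the library total, as their name says. The deposited fraction runs from 0 to 1, and multi-mapping reads were between 2.79% and 3.89% of each library. The design written beforehand took RPKM as the likely unit. As the tables also give estimated counts, the count route named in that design was used, with RPKM as an alternative. How the authors counted limits the values of genes with near-identical copies, and such genes are given as uncertain where most of their reads are shared, as are the RBCS and LHCB1 families by the rule for named genes. Locus tags were matched to the TAIR10.1 annotation for 32709 genes (97.6%), while 809 did not match, and 10662 had a symbol. Coordinates are those of TAIR10.1.

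Estimated counts were rounded to whole numbers and scaled to CPM with TMM factors. Totals ran from 4898426 to 18273148 reads, so that low genes are less precise in the WT control than in the p5cs1-4 control. For each of 15 comparisons of 2 libraries, the log2 ratio of CPM + 1 was taken, and genes with at least 5 CPM in either library and at least 2-fold apart were counted. With 1 library per group no p-value was computed for these. Each fold of a named gene has an exact 95% conditional interval, and a fold against a count of 0 was computed with a floor of 3 counts in that library. The median of each of 22 gene lists (358 genes in 362 entries), over members that reached 5 CPM in any of the 9 libraries, was set beside the medians of 10000 random lists of the same size, matched over 20 bins of mean expression. The lists cover proline metabolism, ABA synthesis and breakdown, clade A protein phosphatases, ABA receptors, dehydration, stress release, fatty acid synthesis, alternative respiration, antioxidant, photosynthesis, glucosinolate, cell wall expansion, aquaporin, jasmonate, salicylate, low-energy, ethylene, flavonoid, heat shock and cell cycle genes, and markers of root and seed.

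An additive model of treatment and genotype was fitted to the 9 libraries with edgeR 4.0.16 (quasi-likelihood test, 4 residual degrees of freedom, mean of at least 1 CPM, Benjamini-Hochberg adjusted p under 0.05). The test moderates the dispersion of each gene with that of all genes, so its p-values do not rest on the 4 residual degrees of freedom alone. Standard errors (SE) were derived from the log2 fold and the F statistic. Lists were tested in it with camera (preset correlation of 0.01, and an estimated correlation) and fry from limma 3.58.1, in R 4.3.3. DESeq2 1.42.0 was the alternative. The lists, designs, alternatives and the rule for named genes were fixed before the data were examined. By that rule the text names P5CS1, ABA2 and PRODH1, for each comparison of 2 libraries the 5 genes with the largest and the 5 with the smallest log2 ratio that have a symbol, up to 4 members of a list with the largest absolute ratio, and in the additive model the 5 higher and 5 lower genes with the smallest adjusted p. In the additive model the list examples are members with the largest fold among those that passed the test, which was settled after the values were seen.

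The additive model was tested on simulated data for labelled release against control with 19485 genes and a dispersion of 0.05. It called 54% of 100 genes changed 2-fold, 100% of 100 genes changed 4-fold and 8 unchanged genes, and 0 genes in the contrast of aba2-1 with WT, which was left unchanged. The simulated change was the same in every genotype, with no interaction of genotype and treatment. These shares therefore need not hold for the real libraries. In counts simulated with counting noise alone, at most 11 of 16358 genes were 2-fold apart in any of the 15 comparisons. The alternatives set beforehand were a pseudocount of 0.1, no floor, a floor of 20 CPM, median-of-ratios scaling, DESeq2, no filter on low values, and each genotype or treatment left out in turn. Reads that map to 1 place only, RPKM as deposited, and the fit without the aba2-1 control library were added after the data were seen. With uniquely assigned reads, genes without such reads in both libraries gave no value, and RPKM list medians were taken relative to the shift of the median of all genes. Those choices were also made after the data were seen.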

Results

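Messenger RNA was sequenced from whole seedlings of Arabidopsis thaliana in 3 genotypes, the wild type Col-0 (WT) and the mutants p5cs1-4 and aba2-1. The p5cs1-4 line is a T-DNA insertion mutant of P5CS1, which encodes the enzyme of the first step of proline synthesis, and aba2-1 is a point mutant of ABA2, which encodes an enzyme of abscisic acid (ABA) synthesis. ABA is the hormone through which plants respond to a shortage of water, and proline is a solute that accumulates in it. Seedlings 7 days old were moved to fresh control plates at a water potential of -0.25 MPa, or to plates with polyethylene glycol at -1.2 MPa, from which water is hard to take up, and were collected after 96 h. A further set went from the stress plates back onto control medium for 10 h, which is called stress release. RNA of 3 experiments was pooled for each genotype and treatment, so each of the 9 groups is 1 library, and no difference between 2 libraries has a replicate check. Reads on the 33518 genes came to 4898426 in the WT control, 8123886 in WT labelled stress and 8792987 in WT labelled release. The aba2-1 libraries held 5558478, 9922020 and 11327500 in the same order, and the p5cs1-4 libraries 18273148, 6917827 and 14580141. Levels are given as CPM, read counts scaled to the size of the library, and log2 ratios are ratios of CPM + 1. Folds carry a 95% interval in brackets that covers counting error only.

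The targeted gene P5CS1 (AT2G39800, a protein-coding gene on chromosome 2, 16598072 to 16603319, minus strand, TAIR10.1) was read in all 9 libraries, the p5cs1-4 libraries included. In WT it stood at 195 CPM in the control, 74.1 CPM in the library labelled stress and 3918 CPM in the library labelled release. In p5cs1-4 the values were 125, 174 and 1199 CPM, and in aba2-1 634, 91.2 and 1389 CPM. Against WT, the mutant p5cs1-4 was 1.56-fold (1.44 to 1.69) lower in the control and 3.27-fold (3.21 to 3.33) lower in labelled release, but 2.35-fold (2.13 to 2.60) higher in labelled stress. A count per gene does not show on which side of the insertion the reads fall, so it tells neither whether full-length transcript was made nor whether the genotype label is right. ABA2 (AT1G52340, protein-coding, chromosome 1, 19489794 to 19491650, minus strand, TAIR10.1) lay between 15.6 and 22.0 CPM in the 9 libraries. A point mutation need not alter the transcript level, so ABA2 does not check the aba2-1 label.

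PRODH1 and the dehydration list, markers chosen before the data were examined, went against the labels of stress and release in every genotype. PRODH1 (AT3G30775, protein-coding, chromosome 3, 12448636 to 12451556, minus strand, TAIR10.1) encodes proline dehydrogenase, the first enzyme of proline breakdown, and is known to be induced on release from low water potential. It was 7.38-fold (6.40 to 8.54) lower in labelled release than in labelled stress in WT, 11.9-fold (10.8 to 13.2) lower in aba2-1 and 11.9-fold (10.6 to 13.5) lower in p5cs1-4. In WT, PRODH1 stood at 187 CPM in the control, 188 CPM in labelled stress and 25.5 CPM in labelled release. Labelled stress exceeded the control 1.54-fold (1.45 to 1.63) in aba2-1 and 1.93-fold (1.81 to 2.05) in p5cs1-4. The WT difference thus came from a low level in labelled release, not from a raised level in labelled stress. The dehydrin gene RAB18 (AT5G66400, protein-coding, chromosome 5, 26518277 to 26519447, minus strand, TAIR10.1), known to be induced by ABA and drought, stood at 13.9 CPM in WT labelled stress and 4950.3 CPM in WT labelled release, and at 81.4 and 4778 CPM in p5cs1-4. In aba2-1 it stood at 252 CPM in the control, 5.15 CPM in labelled stress and 66.2 CPM in labelled release. Of the 28 dehydration genes of the list, 23 were at least 2-fold higher in labelled release than in labelled stress in WT, 14 in aba2-1 and 25 in p5cs1-4. The 9 release markers, 5 of them without uniquely assigned reads, had median log2 ratios of -1.28 in WT, -1.08 in aba2-1 and -0.34 in p5cs1-4 in that comparison. The value of p5cs1-4 lay within the range of random lists. For labelled stress against control the medians were -0.08 in WT and 0.25 in p5cs1-4, both within that range, and 0.39 in aba2-1, outside it. In each genotype the deposited table of the library labelled stress also has a name that ends in R, and that of the library labelled release a name that ends in S. The libraries are therefore named by their labels throughout, and each direction below holds for the labelled library, not for stress or release itself.

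**Figure D1:**
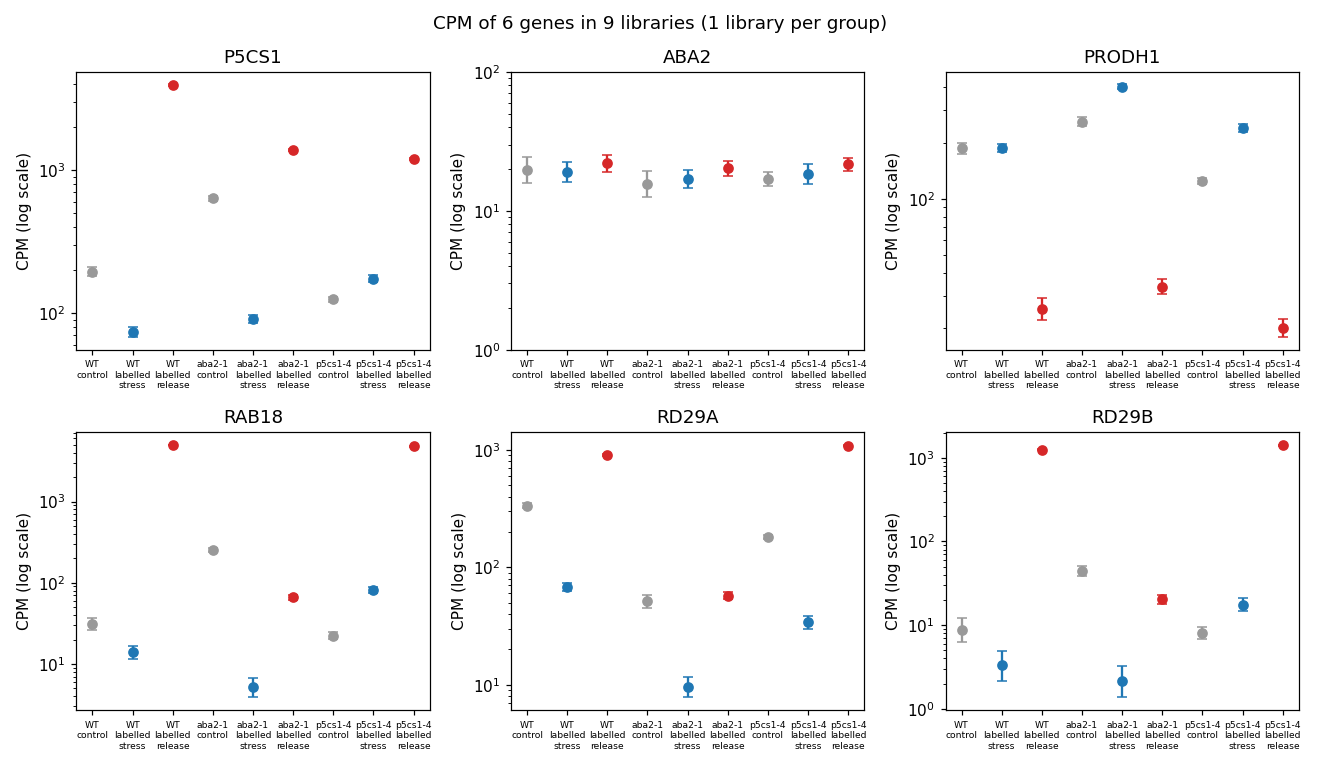
CPM on a log axis of 6 marker genes in the 9 libraries, grouped by genotype, with bars for the 95% counting interval. RAB18 stands at 4950.3 CPM in WT labelled release and 4778 CPM in p5cs1-4 labelled release, against 66.2 CPM in aba2-1 labelled release.

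Between 2 libraries, a gene counted as higher or lower when it differed at least 2-fold and reached 5 CPM in either library. Labelled release against control gave the most such genes in WT, 2125 higher and 2348 lower among 16719 past that floor. The same contrast gave 1408 higher and 1976 lower in p5cs1-4 and 753 higher and 928 lower in aba2-1. Labelled stress against control gave 723 higher and 664 lower in WT, 739 and 585 in aba2-1, and 662 and 960 in p5cs1-4. The balance of higher and lower genes depended on the setting. With a floor of 20 CPM the 723 and 664 genes of WT labelled stress became 154 and 263, so that 36.9% were higher against 52.1%. That floor also turned labelled stress against control in aba2-1 from 55.8% to 45.9% higher and aba2-1 against WT in labelled stress from 50.6% to 43.0%. With the deposited RPKM 57.4% of the genes of WT labelled release against control were higher, against 47.5%, without a floor 52.2% and with a floor of 20 CPM 40.3%. The deposited RPKM gave 59.7% for WT labelled stress against control. Medians of gene lists below lay outside the central 95% of the medians of 10000 random lists of the same size and expression, unless stated otherwise. That range describes variation between genes, not between replicate libraries. UBQ6, TPS-CIN (2 loci) and PGLP1 ranked among the most different genes in several comparisons. EXO70H6 did so only for WT labelled stress against control, and SAE1B only for p5cs1-4 against WT in the control. Up to all reads of these genes mapped to several places, so their values are uncertain. UBQ6, for example, was listed at 0 in 6 libraries and at 85.9, 86.8 and 134 CPM in WT labelled stress, WT labelled release and the aba2-1 control.

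**Figure D2:**
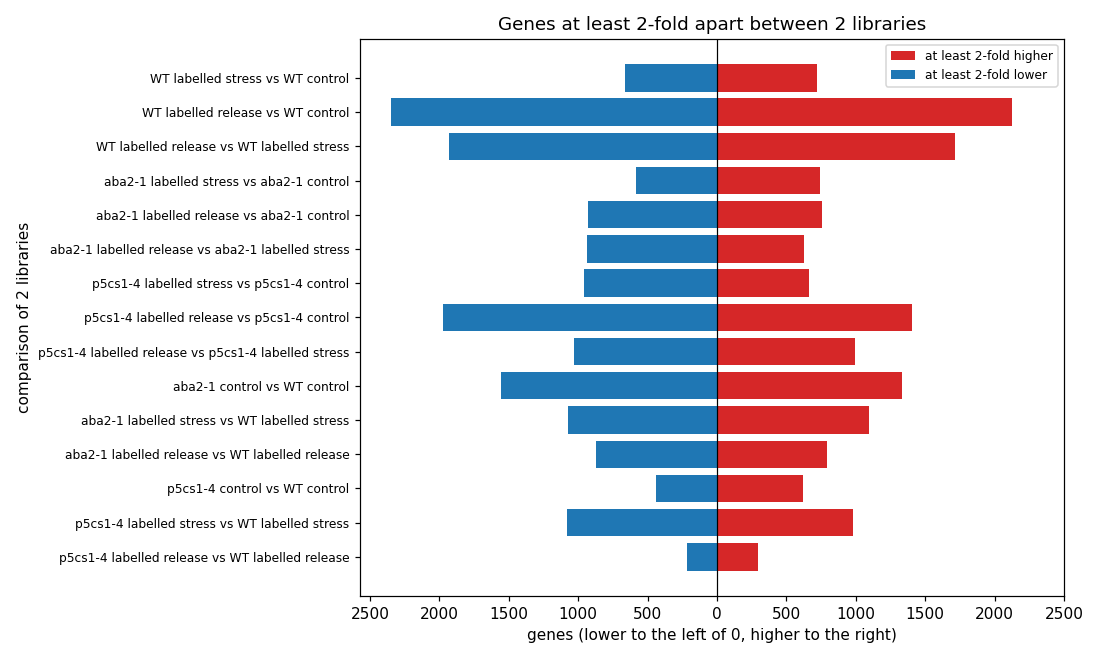
Number of genes at least 2-fold lower (left of 0) and higher (right of 0) in each of the 15 comparisons of 2 libraries. Labelled release against control in WT has 2125 higher and 2348 lower, and labelled release of p5cs1-4 against WT has 294 higher and 218 lower.

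Labelled stress against control asks which transcripts differ after 96 h. In WT, genes linked to dehydration and ABA were lower in the library labelled stress: the cold- and drought-induced gene COR15A was 11.9-fold (6.48 to 24.1) lower and AFP1, whose product binds an ABA-responsive transcription factor, 15.6-fold (8.08 to 33.6) lower. The cystatin gene CYS2 was 23.9-fold (8.81 to 90.9) lower. ROPGEF12, with no reads in labelled stress, was at least 19.5-fold lower. Of the 28 dehydration genes, 15 were at least 2-fold lower and 0 higher, with a median log2 ratio of -1.09. KIN2 stood at -2.65 and RD29A at -2.29. Jasmonate genes were lower too (9 of 18, median -0.97), with LOX4 at -2.40 and VSP2 at -1.89. Higher were BGLU28, at 0.233 CPM in the control and 12.8 CPM in labelled stress, and UGT71C2, at 0.233 and 12.4 CPM. The flavonoid regulator MYB111, with no reads in the control, was at least 10.5-fold higher against a floor of 3 counts, used for each fold given as at least. The floral gene PI went from 0.233 to 8.16 CPM. Smaller list medians were those of the ABA synthesis and breakdown genes (-0.57), the clade A protein phosphatases that hold back ABA signalling (-0.68), the glucosinolate genes (-0.32) and the flavonoid genes (-0.52, but -1.05 with a pseudocount of 0.1 and -0.22 with uniquely assigned reads), and, on the higher side, the ABA receptors (0.42) and the ethylene genes (0.56).

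In aba2-1, labelled stress against control gave lower lipid transfer protein genes LTP4, by 159-fold (113 to 233), and LTP3, by 119-fold (75.0 to 202), and RAB18 was 48.8-fold (37.3 to 65.2) lower. The dehydration list had 15 of 28 members lower and 0 higher (median -1.07), and the flavonoid list 12 of 16 lower (median -1.74), with CHS, the entry enzyme of flavonoid synthesis, at -2.07. Against the WT control, the flavonoid median was 3.70 in the aba2-1 control and 2.46 in aba2-1 labelled stress, so both libraries stood above it. On the higher side, the glucanase gene PR2 was 16.7-fold (11.1 to 26.2) higher and the aminotransferase gene TAT3 11.6-fold (9.42 to 14.5) higher. MRD1, with no reads in the control and up to 0.884 of its reads shared with other genes, was at least 34.5-fold higher. Of the jasmonate genes 9 of 18 were at least 2-fold higher (median 1.09), JAZ10 at 2.06, and of the salicylate genes 4 of 12 (median 0.81), WRKY70 at 2.17. Photosynthesis genes had a median of -0.59 and aquaporins of -0.63, while the low-energy genes had one of 0.48, the phosphatases -1.19, the glucosinolate genes -0.35, the ABA receptors 0.48 and the release markers 0.39 (0.95 with uniquely assigned reads). Of the genes at least 2-fold apart, 55.8% were on the higher side, against 69.0% with the deposited RPKM and 45.9% with a floor of 20 CPM.

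In p5cs1-4, the library labelled stress carried more transcript of anthocyanin synthesis than its control. UGT79B1 was 97.3-fold (57.5 to 179) higher, LDOX 50.6-fold (40.8 to 63.6), DFR 43.0-fold (35.1 to 53.3) and UGT75C1 40.6-fold (31.6 to 53.1), all encoding enzymes of that pathway, and 13 of 16 flavonoid genes were at least 2-fold higher (median 2.43). LTP4 was 99.8-fold (72.7 to 141) higher. Lower were the defence genes PCC1, from 70.5 to 0.405 CPM with up to 0.657 of its reads shared with other genes, and LURP1, by 36.9-fold (18.6 to 85.8), and the transcription factor genes ORA47, by 21.9-fold (13.8 to 37.1), RRTF1, by 16.1-fold (11.6 to 23.1), and DDF1, by 24.5-fold (11.8 to 61.2). Jasmonate genes were lower in 11 of 18 cases (median -1.28), LOX3 at -3.42, and photosynthesis genes in 15 of 34 (median -0.92). Beside these, 5 of 7 root markers were at least 2-fold higher (median 1.62), EXPA7 at 3.06. The other lists outside the random range were glucosinolate (-0.63), salicylate (-0.54), low-energy (-0.38) and fatty acid genes (-0.31), whereas the dehydration median was 0.05, within it. Of the genes at least 2-fold apart, 40.8% were higher, 56.3% with the deposited RPKM and 34.4% with a floor of 20 CPM.

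In WT the library labelled release carried dehydration transcripts far above the control. The lipid transfer protein genes LTP4 and LTP3 were 763-fold (469.5 to 1334) and 337-fold (193 to 652) higher, the late embryogenesis abundant gene LEA7 286-fold (181 to 483), RAB18 157-fold (133 to 188) and TSPO, a membrane protein gene induced by stress, 338-fold (116 to 1643). Of the 28 dehydration genes 22 were at least 2-fold higher and 2 lower (median 1.85), all 8 clade A phosphatases were higher (median 2.87), HAI1 at 5.32, and all 16 flavonoid genes were higher (median 4.13), DFR at 6.15. Among the lowest ratios, the cell wall enzyme gene XTH6 was 117-fold (61.4 to 258) lower, the peroxidase gene PRXCA 74.2-fold (35.5 to 186), TBL45 58.1-fold (30.1 to 129), the lipoxygenase gene LOX3 29.2-fold (24.0 to 35.8) and the transcription factor gene RAV1 29.9-fold (23.8 to 38.1). Photosynthesis genes were lower in 30 of 34 cases (median -1.32), cell wall expansion genes in 11 of 19 (median -1.80), aquaporins in 11 of 17 (median -1.45), glucosinolate genes in 15 of 23 (median -1.15) and jasmonate genes in 13 of 18 (median -1.79). Examples are LHCB1.4 at -4.33 and RBCS2B at -3.79, both of families with near-identical copies and so uncertain, EXPA8 at -4.28, TIP2;1 at -4.31 and IMD1 at -1.99. The thionin gene THI2.1 went the other way from most jasmonate genes, at 5.01, and the aquaporin PIP2;5 stood at 3.09.

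Further lists in the same WT comparison were the ABA synthesis and breakdown genes (median 1.38), with CYP707A1 at 2.56 and CYP707A3 at -2.11, both encoding enzymes that break down ABA. The ABA receptors had a median of -1.23, PYL4 at -3.61, the release markers -1.49 (5 of the 9 are bZIP genes with no reads of their own, so uncertain, and uniquely assigned reads gave -2.29), fatty acid genes -0.53, heat shock genes 1.38 (2.45 with a pseudocount of 0.1), HSP22 at 4.85, and cell cycle genes -0.90. Within the random range were proline metabolism (0.28), where P5CS1 stood at 4.32 and PRODH1 at -2.83, alternative respiration (-0.08), antioxidant (-0.09), salicylate (0.52), low-energy (-0.54) and ethylene genes (0.13), root markers (1.01) and the 3 seed markers that passed the floor (2.70). The seed marker median lay at the upper edge of that range and was 4.12 with a pseudocount of 0.1. The median level of the photosynthesis genes went from 2210.1 CPM in the WT control to 792 CPM.

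The p5cs1-4 library labelled release also carried dehydration transcripts far above its control. LTP4 was 1019-fold (746 to 1434) higher, LEA7 529-fold (397 to 723), LTP3 402-fold (302 to 547), RAB18 213-fold (193 to 237) and RD29B 175-fold (148 to 209). Lower were XTH6, by 123-fold (70.4 to 239), the germin-like genes GER1, by 39.7-fold (34.2 to 46.4), and GER3, by 36.3-fold (30.8 to 43.0), and the defence regulator ACD6, by 58.1-fold (38.6 to 92.0). PCC1, uncertain for its shared reads and with no reads in labelled release, was at least 359.6-fold lower. Dehydration genes were higher in 22 of 28 cases (median 2.37), flavonoid genes in all 16 (median 3.83) and phosphatases in 7 of 8 (median 2.49). Photosynthesis genes were lower in 32 of 34 (median -1.37), glucosinolate genes in 18 of 23 (median -1.25), aquaporins in 11 of 17 (median -1.37) and cell wall genes in 11 of 19 (median -1.55). Medians of the other lists outside the random range were 1.12 for ABA synthesis and breakdown, -1.44 for ABA receptors, 0.42 for proline metabolism, -0.85 for release markers (-1.33 with uniquely assigned reads), -0.76 for fatty acid, -0.83 for jasmonate, 0.80 for heat shock and -0.56 for cell cycle genes, and 2.38 for seed markers (3.95 with a pseudocount of 0.1). Of the genes at least 2-fold apart, 41.6% were higher, 51.9% with the deposited RPKM and 36.3% with a floor of 20 CPM.

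In aba2-1 the dehydration list did not stand apart in labelled release against control: 1 of 28 genes was at least 2-fold higher and 6 were lower (median -0.30, within the random range). The higher genes were led by BHLH100, by 30.6-fold (16.0 to 67.3), bHLH38, by 19.6-fold (12.4 to 32.6), and bHLH39, by 26.5-fold (12.7 to 66.3), which encode transcription factors of the iron deficiency response. Lower were the peroxidase gene PRX52, by 56.0-fold (32.9 to 104), the gibberellin-responsive gene GASA1, by 29.7-fold (26.7 to 33.1), ELI3-2, by 88.4-fold (37.2 to 276), and the carnitine transporter gene OCT3, by 21.1-fold (14.5 to 31.7). PRODH1 was 7.77-fold (6.97 to 8.67) lower and P5CS1 2.19-fold (2.11 to 2.27) higher. Flavonoid genes were lower in 11 of 16 (median -1.62, with medians against the WT control of 3.70 in the aba2-1 control and 2.55 in labelled release), glucosinolate genes in 11 of 23 (median -0.95), aquaporins in 8 of 17 (median -0.98), and heat shock genes in 5 of 10 (median -1.03). Antioxidant genes had a median of -0.78, APX1 at -1.80, cell wall genes -0.40, root markers -0.67 and release markers -0.50 (-0.78 with uniquely assigned reads), while low-energy (0.76), salicylate (0.40) and jasmonate genes (0.21) were on the higher side. Of the genes at least 2-fold apart, 44.8% were higher, 64.1% with the deposited RPKM and 28.2% with a floor of 20 CPM.

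**Figure D3:**
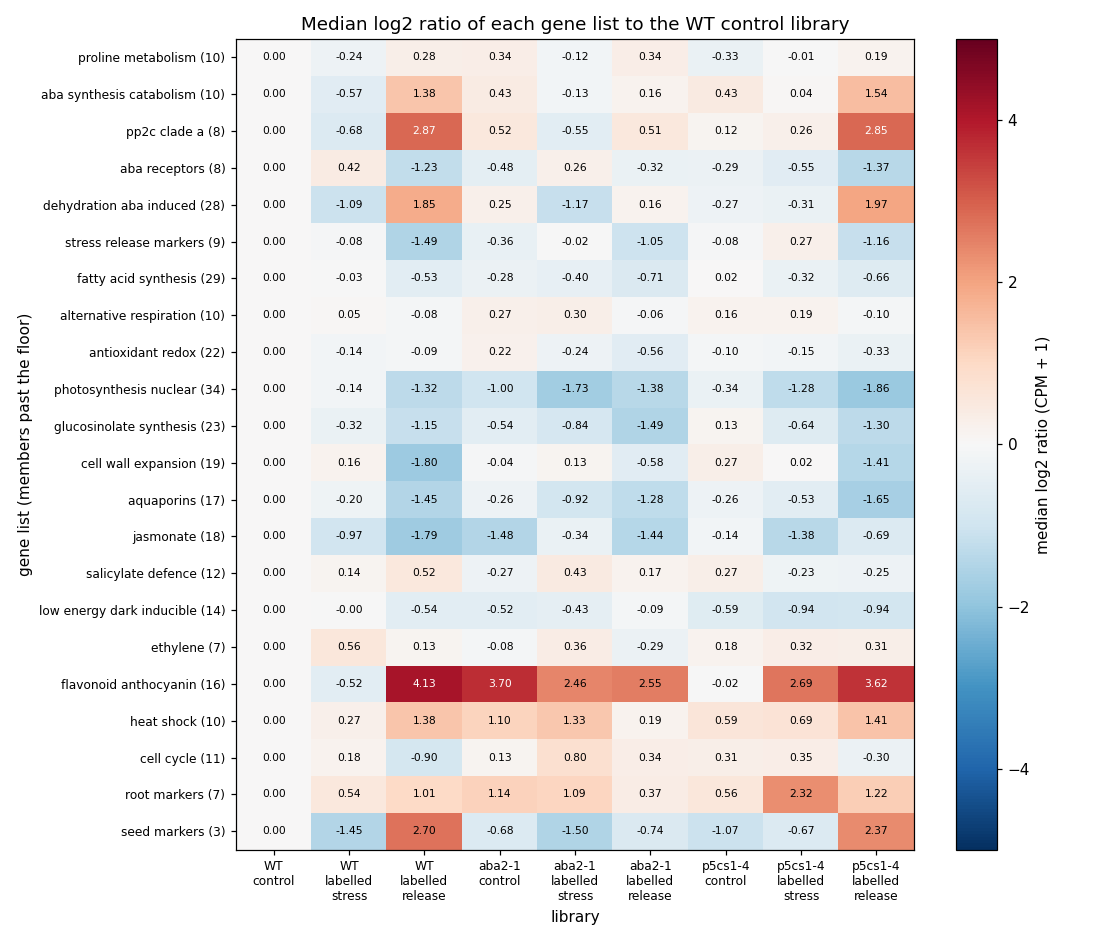
Median log2 ratio of each library against the WT control for the 22 gene lists (rows, with the number of measured members in brackets) in the 9 libraries (columns), as a colour scale. The flavonoid list stands at 4.13 in WT labelled release and at 3.70 in the aba2-1 control.

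Labelled release against labelled stress compares seedlings 10 h apart in handling after the same 96 h. In WT, LTP4 was 900.01-fold (605 to 1405) higher in labelled release, LEA7 912-fold (496 to 1903), LTP3 447-fold (275 to 783), RD29B 381-fold (258 to 589.6) and RAB18 355-fold (293 to 434), while TBL45 was 93.5-fold (49.0 to 205) lower, PRXCA 122-fold (58.8 to 304) and XTH6 69.0-fold (36.1 to 152). The receptor kinase gene CRK30 stood at 68.0 CPM in labelled stress and 0.230 CPM in labelled release, and the ABA receptor gene PYL6 had no reads in labelled release and was at least 154-fold lower. The WT medians were 2.82 for dehydration, 4.59 for flavonoid, 3.50 for phosphatase, 1.98 for ABA synthesis and breakdown and 1.31 for heat shock genes, and 3.25 for seed markers, EM1 at 5.11, the last 2 lists at 2.09 and 6.43 with a pseudocount of 0.1. On the lower side they were -1.81 for ABA receptors, -1.34 for cell wall, -1.28 for release markers, -1.23 for photosynthesis, -1.14 for aquaporins, -1.02 for cell cycle, -0.90 for glucosinolate, -0.79 for jasmonate and -0.53 for fatty acid genes. The counts were 1718 higher and 1932 lower in WT (47.1% higher, 51.5% with the deposited RPKM and 44.6% with a floor of 20 CPM), 629 and 937 in aba2-1 and 992 and 1030 in p5cs1-4.

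In p5cs1-4, RD29B was 80.6-fold (67.8 to 96.5) higher in labelled release than in labelled stress, LEA4-5 98.4-fold (59.5 to 176), LEA7 70.4-fold (60.0 to 83.2), RAB18 58.7-fold (54.2 to 63.7) and TSPO 51.1-fold (35.1 to 77.7). The lipid transfer protein gene AZI1 was 41.3-fold (30.5 to 57.3) lower, GASA1 32.0-fold (28.7 to 35.7), GER1 31.1-fold (26.7 to 36.5), XTH6 50.4-fold (28.4 to 98.7) and PRX52 26.1-fold (17.9 to 39.6). Dehydration genes had a median of 2.201 and phosphatases of 2.11, but jasmonate genes one of 0.74, THI2.1 at 2.85 and JAZ7 at 2.04. Other medians were 0.72 for ABA synthesis and breakdown, 0.92 for heat shock and 2.42 for seed markers, and below 0 -1.37 for ABA receptors, -1.26 for cell wall, -0.99 for aquaporins, -0.89 for root markers, -0.84 for cell cycle, -0.58 for glucosinolate, -0.51 for photosynthesis and -0.40 for fatty acid genes.

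In aba2-1, P5CS1 itself was among the genes with the highest ratios, 15.2-fold (14.3 to 16.3) higher in labelled release than in labelled stress, with LTP3 19.9-fold (12.4 to 33.9) higher. The arabinogalactan protein gene AGP30 had 1 read in labelled stress and a ratio of 181-fold (32.1 to 7162), and M17 was 33.2-fold (17.3 to 73.2) higher with up to 0.833 of its reads shared with other genes. Lower were TAT3 by 125-fold (80.8 to 205), JRG21 by 26.5-fold (22.1 to 32.0) and the terpene synthase gene TPS04 by 41.0-fold (24.2 to 75.5), as were DIR5 by 69.9-fold (33.6 to 175) and PRX52 by 53.4-fold (31.6 to 98.3). The dehydration median was 0.94 with 14 of 28 genes higher, GOLS2 at 3.18, and the phosphatase median 0.70. Heat shock genes had a median of -1.24, release markers -1.08 (-2.07 with uniquely assigned reads), ABA receptors -0.89, jasmonate genes -0.85, root markers -0.69, glucosinolate genes -0.64, cell cycle genes -0.42, salicylate genes -0.39, antioxidant genes -0.34 and fatty acid genes -0.29.

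The comparison of aba2-1 with WT asks which transcripts differ when ABA synthesis is impaired. In labelled release, the dehydration genes were lower in aba2-1: RAB18 was 74.8-fold (69.8 to 80.1) lower, LTP4 68.8-fold (63.1 to 75.1), LEA7 63.4-fold (55.8 to 72.3) and RD29B 61.7-fold (54.5 to 70.0). Of the 28 dehydration genes 23 were at least 2-fold lower and 0 higher (median -2.11), of the phosphatases all 8 (median -2.68), of the flavonoid genes 14 of 16 (median -2.01) and of the heat shock genes 7 of 10 (median -1.51). Higher were 10 of 19 cell wall genes (median 1.005, EXPA8 at 2.83) and 7 of 11 cell cycle genes (median 1.15, AUR1 at 1.64), and the ABA receptors had a median of 1.25, PYL6 at 2.92. The iron regulators bHLH39 and BHLH100 were 27.3-fold (15.1 to 55.1) and 12.4-fold (8.88 to 17.9) higher. MRD1, uncertain for its shared reads and with no reads in WT, was at least 36.6-fold higher. The amylase gene BAM5, with 3 reads in WT, gave a ratio of 45.5-fold (15.3 to 222). Further medians were -0.76 for ABA synthesis and breakdown, -0.65 for salicylate, PR1 at -4.39, -0.34 for antioxidant, -2.69 for seed markers, 0.42 for jasmonate, 0.36 for low-energy and 0.21 for aquaporins. The counts were 796 higher and 873 lower, 47.7% higher against 60.1% with the deposited RPKM and 35.0% with a floor of 20 CPM.

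In the control libraries, aba2-1 carried far more transcript of anthocyanin synthesis than WT, 15 of 16 flavonoid genes at least 2-fold higher (median 3.70), UGT75C1 at 5.71 and DFR at 5.62. LTP4 was 128-fold (78.8 to 225) higher, the nitrilase gene NIT2 77.1-fold (49.2 to 128), and EARLI1, with 1 read in WT, gave a ratio of 524-fold (93.8 to 20747). PRX52 had no reads in WT and was at least 87.4-fold higher. Lower were LOX3, by 17.35-fold (14.3 to 21.2), the methyltransferase gene FAMT, by 17.1-fold (11.2 to 27.4), and RRTF1, by 48.0-fold (20.2 to 149.6). The jasmonate list was lower in 13 of 18 (median -1.48) and the photosynthesis list in 16 of 34 (median -0.995), beside root markers at a median of 1.14 (2.04 with a pseudocount of 0.1). Heat shock genes had a median of 1.099, phosphatases 0.52 (0.96 with a pseudocount of 0.1), dehydration genes 0.25, glucosinolate genes -0.54 and low-energy genes -0.52. The counts were 1333 higher and 1555 lower, 46.2% higher against 56.3% with the deposited RPKM and 40.7% with a floor of 20 CPM. Across genes, the aba2-1 control library correlated more closely with p5cs1-4 labelled stress (r = 0.968) than with the WT control (r = 0.908). The p5cs1-4 library labelled stress also correlated more closely with aba2-1 labelled stress (r = 0.965) and labelled release (r = 0.953) than with its own control (r = 0.940) and labelled release (r = 0.922). Such pairs were not limited to these libraries. WT labelled stress correlated more closely with the p5cs1-4 control (r = 0.969) than with the WT control (r = 0.952).

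In labelled stress, EARLI1 was 79.4-fold (50.7 to 132) higher in aba2-1 than in WT, the proteinase inhibitor gene UPI 74.2-fold (49.7 to 116), JRG21 54.7-fold (39.2 to 78.7) and NATA1 94.7-fold (43.3 to 259), and LDOX, of anthocyanin synthesis, was 117-fold (56.4 to 291) higher. Jasmonate genes were higher in 9 of 18 (median 0.72), VSP1 at 4.28, salicylate genes in 3 of 12 (median 0.77), PR2 at 3.50, and flavonoid genes in 11 of 16 (median 2.01). Photosynthesis genes were lower in 31 of 34 (median -1.53), LHCB1.4, uncertain for its near-identical copies, by 10.7-fold (10.1 to 11.3). NEET, an iron-sulphur protein gene, was lower by 22.7-fold (17.7 to 29.6), and the pectin methylesterase gene ATPMEPCRD by 26.4-fold (16.7 to 44.4). Other medians were 0.69 for heat shock (1.54 with a pseudocount of 0.1), 0.86 for release markers, 0.49 for proline metabolism, 0.43 for alternative respiration, AOX1D at 2.72, -0.81 for aquaporins, -0.62 for glucosinolate, -0.49 for ABA receptors and -0.47 for antioxidant genes. The counts were 1098 higher and 1073 lower, 50.6% higher against 66.4% with the deposited RPKM and 43.0% with a floor of 20 CPM.

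The comparison of p5cs1-4 with WT asks which transcripts differ when proline synthesis is impaired. The libraries labelled release differed by 294 genes higher and 218 lower, the fewest of the 15 comparisons, or 76 and 89 with a floor of 20 CPM (46.1% higher against 57.4%, and 66.2% with the deposited RPKM). None of the 28 dehydration genes differed 2-fold (median 0.12). Of the salicylate genes, 5 of 12 were at least 2-fold lower in p5cs1-4 (median -0.75). Among single genes, PR1 was 128-fold (71.2 to 257) lower and LURP1 123-fold (75.7 to 217) lower. PCR1 went from 16.2 to 0.196 CPM, and PCC1, uncertain for its shared reads, had no reads in p5cs1-4 and was at least 59.8-fold lower. Jasmonate genes were higher in 9 of 18 (median 1.07), JAZ10 by 14.5-fold (8.18 to 28.4). The potassium transporter gene HAK5 was 12.8-fold (7.52 to 23.7) higher, SRO5 9.29-fold (6.15 to 14.7) and MSRB7 6.65-fold (4.73 to 9.63). SRO5 overlaps P5CDH in antisense, and the counting is not stated to use strand, so its reads are uncertain. Smaller medians were -0.56 for photosynthesis, -0.44 for flavonoid and -0.44 for low-energy genes, and 0.48 for cell cycle, 0.40 for cell wall and 0.31 for release marker genes (0.65 with uniquely assigned reads).

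In the control libraries, p5cs1-4 and WT differed by 620 higher and 437 lower genes, 58.7% higher. With a floor of 20 CPM the counts were 132 and 174, 43.1% higher, and the deposited RPKM gave 64.5% higher. The dehydrogenase gene HSD2 was 11.4-fold (5.18 to 31.4) higher and SRO5 5.50-fold (3.34 to 9.74), while EARLI1, with 1 read in WT, ZPR1 and the iron transporter gene IRT1, with 2 reads each, gave ratios of 34.9-fold (6.16 to 1389), 18.6-fold (5.06 to 155) and 11.4-fold (3.06 to 95.5). The phosphate transporter gene PHT3;3 was 5.84-fold (4.22 to 8.12) lower, GLIP4 16.5-fold (6.59 to 49.1) and DRP4D 13.2-fold (6.10 to 31.5), the last with up to 0.851 of its reads shared with other genes. ROPGEF12 had 2 reads in p5cs1-4 and was 65.2-fold (16.7 to 561) lower. The medians were -0.59 for low-energy genes, SEN1 at -1.37, -0.34 for photosynthesis, -0.33 for proline metabolism, -0.27 for dehydration and -0.26 for aquaporins, and 0.59 for heat shock, 0.43 for ABA synthesis and breakdown and 0.27 for cell wall genes.

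In labelled stress, p5cs1-4 exceeded WT in anthocyanin synthesis: LDOX was 279-fold (135 to 694) higher, UGT75C1 116-fold (63.1 to 243) and DFR 85.9-fold (56.6 to 137), TT19, with 3 reads in WT, 210.3-fold (71.6 to 1023) and UGT79B1, with 2, 305-fold (84.1 to 2526). Flavonoid genes were higher in 14 of 16 (median 2.83) and dehydration genes in 11 of 28 (median 0.48), LTP4 at 5.79 and COR15A at 3.35. Lower were the cytochrome P450 gene CYP71B22, by 22.0-fold (12.7 to 41.8), PRXCA, by 14.2-fold (10.7 to 19.3), CRK4, with 3 reads in p5cs1-4, by 40.3-fold (13.5 to 198), and the transporter gene UMAMIT17, with 2, by 49.7-fold (13.4 to 416). Photosynthesis genes were lower in 22 of 34 (median -1.104) and root markers higher in 5 of 7 (median 2.23), their median level being 0.789 CPM in WT and 7.29 CPM in p5cs1-4. Other medians were 1.06 for phosphatases, HAI2 at 3.76, 0.53 for ABA synthesis and breakdown, -1.06 for ABA receptors, -0.71 for low-energy, -0.50 for glucosinolate and -0.41 for jasmonate genes. The counts were 981 higher and 1079 lower, 47.6% higher against 61.5% with the deposited RPKM and 39.4% with a floor of 20 CPM.

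The genotypes share no library in their treatment comparisons, so the overlap of their responses can be set beside that of independent lists. That is a low bar, as genes that vary between libraries can raise shared and opposite counts alike. No number for independent lists was computed for opposite genes, so an excess of shared genes alone does not show a shared response. For labelled release against control, WT and p5cs1-4 shared 1028 higher genes, where independent lists would share 158, and 1419 lower genes, where they would share 253. Of the WT higher genes 5 were lower in p5cs1-4, and of the WT lower genes 5 were higher. WT and aba2-1 shared 200 higher and 292 lower genes in that contrast, against 71.0 and 109. Of the WT higher genes 170 were lower in aba2-1, and of the WT lower genes 103 were higher. For aba2-1 and p5cs1-4 the shared genes were 184 and 320, against 49.4 and 94.3. Of the aba2-1 higher genes 62 were lower in p5cs1-4, and of the lower ones 132 were higher. For labelled release against labelled stress, WT and p5cs1-4 shared 622 higher and 652 lower genes, against 91.8 and 96.2, WT and aba2-1 279 and 386, against 51.7 and 88.2, and the mutants 320 and 382, against 28.3 and 50.5. Genes higher in the first and lower in the second numbered 31, 91 and 3 for these pairs, and the reverse 13, 26 and 19. For labelled stress against control the shared higher genes were 87 for WT and aba2-1, 91 for WT and p5cs1-4 and 89 for the mutants, against 22.9, 15.8 and 24.2. The shared lower genes of that contrast were 48, 130 and 58, against 14.5, 29.5 and 26.3. Against these, 10 of the WT higher genes were lower in aba2-1 and 20 in p5cs1-4. Of the WT lower genes 68 and 37 were higher there, and the 68 of aba2-1 outnumbered the 48 shared. Between the mutants the opposite genes outnumbered the shared ones on both sides: 170 of the aba2-1 higher genes were lower in p5cs1-4, and 115 of the lower ones higher. The aba2-1 control and p5cs1-4 labelled stress libraries, which correlated at r = 0.968, enter that comparison on opposite sides of the ratio. Across genes, which are not independent replicates, the log2 ratios of labelled release to control correlated at r = 0.847 between WT and p5cs1-4 at 0.140 between WT and aba2-1 and at 0.214 between the mutants. Those of labelled release to labelled stress, which do not use the aba2-1 control library, correlated at 0.704, 0.436 and 0.641 in the same order, and those of labelled stress to control at 0.204, 0.166 and -0.111.

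A model with treatment and genotype as additive terms, fitted to all 9 libraries, tests whether a treatment difference exceeds its spread over the 3 genotypes (edgeR quasi-likelihood test, 4 residual degrees of freedom, Benjamini-Hochberg adjustment over 19600 genes). The spread of each gene is moderated with that of all genes. From control to labelled release, PRODH1 fell by 2.83 ± 0.22 (log2 fold ± SE, adjusted p = 0.00950) and NCED3, which encodes the enzyme of the committed step of ABA synthesis, rose by 1.69 ± 0.19 (adjusted p = 0.0147), each in the same direction in 3 of 3 genotypes. SIS, a gene linked to salt tolerance, rose by 3.66 ± 0.27, the thiol peroxidase gene TPX2 (AT1G65970, up to 0.311 of its reads shared) by 2.74 ± 0.21, ATC by 3.61 ± 0.38 and the dioxygenase gene DOX1 by 1.54 ± 0.15, while OCT3 (-4.27 ± 0.33), the cell wall glycoprotein gene FLA13 (-4.50 ± 0.38), ENH1 (-2.21 ± 0.19) and IMD1 (-1.98 ± 0.16) fell, with adjusted p between 0.00950 and 0.0147. In all, 350 genes rose and 773 fell. From labelled stress to labelled release 301 rose and 429 fell, among them NCED3 at 3.07 ± 0.20 (adjusted p = 0.00475), SIS at 3.99 ± 0.27, the ABA-responsive transcription factor gene ABF3 at 1.64 ± 0.13, TPX2 at 2.28 ± 0.20 and the sulphate transporter gene SULTR3;1 at 2.24 ± 0.20. The lower genes were led by MIOX2, an inositol oxygenase gene, at -2.92 ± 0.17, PRODH1 at -3.36 ± 0.22 (adjusted p = 0.00475), OCT3 at -3.90 ± 0.32, FLA13 at -4.33 ± 0.37 and LRX3 at -2.45 ± 0.24. For both contrasts edgeR called 0 genes without the WT libraries (3150 and 2969 at an unadjusted p under 0.05) and 0 without the p5cs1-4 libraries (2345 and 2391), and DESeq2 was not run on these subsets. Without the aba2-1 libraries the counts of genes that rose and fell were 1524 and 2309 for labelled release against control and 802 and 1091 for labelled release against labelled stress. Without the aba2-1 control library alone they were 1242 and 1745, and 820 and 1035. DESeq2 gave 1292 and 1992, and 1120 and 1461.

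Among the gene lists, 16 of 24 glucosinolate genes fell from control to labelled release (17 fell and 1 rose adjusted over the list alone), CYP79F1 at -2.54 ± 0.30 and FMO-GSOX1 at -2.46 ± 0.32, both encoding enzymes of the pathway. Of the aquaporins 9 of 18 fell (11 fell and 1 rose adjusted over the list alone), TIP2;1 at -3.41 ± 0.45 and PIP1;5 at -2.52 ± 0.56. Of the cell wall genes 7 of 19 fell and 2 rose (8 and 5 adjusted over the list alone), XTH16 at -3.37 ± 0.63 and XTH19 at 1.82 ± 0.34. Antioxidant genes fell in 7 of 22 cases (9 fell and 1 rose adjusted over the list alone), 2CPB at -1.98 ± 0.44, photosynthesis genes in 6 of 34 (21 adjusted over the list alone) and fatty acid genes in 4 of 29 (16 adjusted over the list alone). From labelled stress to labelled release 8 of 28 dehydration genes rose (22 adjusted over the list alone), RD29A by 3.89 ± 0.50 and GOLS2 by 3.57 ± 0.51, and P5CS1 rose by 4.14 ± 0.85 (adjusted p = 0.0471). With a preset correlation of 0.01, limma's camera called between 7 and 15 lists in each contrast, but with an estimated correlation no list was called in any contrast, the smallest being adjusted p = 0.249 for the glucosinolate list from control to labelled release. The fry test, which asks whether a list moves on balance in 1 direction, gave adjusted p = 0.0124 for that list, 0.0282 for aquaporins and 0.0394 for fatty acid genes in the same contrast, and no value under 0.05 in the other contrasts. Median and mean log2 fold of a list differed in sign for 4 lists from control to labelled release: proline metabolism (median 0.15, mean -0.11), alternative respiration (-0.22 and 0.34), low-energy (-0.16 and 0.29) and heat shock genes (-0.14 and 1.19). From labelled stress to labelled release they did so for alternative respiration (-0.08 and 0.28), salicylate (-0.22 and 0.33), low-energy (-0.01 and 0.13) and ethylene genes (0.13 and -0.02). From control to labelled stress they did so for alternative respiration (-0.01 and 0.06), and for aba2-1 against WT for release markers (-0.04 and 0.19) and low-energy genes (-0.06 and 0.12). The direction given by camera was that of the mean in these cases, except for alternative respiration from control to labelled stress and low-energy genes of aba2-1 against WT, where it was down. It was also down for the heat shock genes from labelled stress to labelled release, whose median was 0.27 and mean 0.56, and none of these 3 was called.

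No gene passed the threshold for labelled stress against control (0 genes with edgeR, 1617 at an unadjusted p under 0.05, 29 higher and 38 lower with DESeq2), and the smallest adjusted p was 0.323. The genes with the smallest p were ERF8 at -1.66 ± 0.18, NCED3 at -1.38 ± 0.20 and MIOX2 at 1.395 ± 0.16. For aba2-1 against WT edgeR called 0 genes as well (2875 at an unadjusted p under 0.05, 246 higher and 285 lower with DESeq2), with MIOX2 at 1.57 ± 0.16, ADR1 at 1.33 ± 0.16 and ENH1 at -1.61 ± 0.19 among the smallest p, and leaving out the aba2-1 control library gave 1 lower gene. For p5cs1-4 against WT it called 0 (2107 at an unadjusted p under 0.05, 81 higher and 76 lower with DESeq2), with MSL9 at 1.79 ± 0.27 and UGT74F2 at -0.86 ± 0.15 among the smallest p. In these contrasts 6 of 28 dehydration genes and 7 of 24 glucosinolate genes fell, and 1 glucosinolate gene rose, from control to labelled stress when adjusted over the list alone, and 6 and 8 were lower in aba2-1 than in WT. Adjusted in that way, 2 cell cycle genes were higher in aba2-1, as were 2 cell wall genes, with 1 cell wall gene lower. Of the ABA synthesis and breakdown genes, antioxidant genes and seed markers 2 each were lower in aba2-1, as was 1 aquaporin. The residual of this model holds the interaction of genotype and treatment together with library noise, so a gene that responds in some genotypes only has a large spread in it.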

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

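The tests of carry-over and of exchanged aba2-1 control and p5cs1-4 labelled stress libraries were chosen after the result was seen. The tests of exchanged stress and release labels and of another genotype in the aba2-1 control library were written before.

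PRODH1 was at least 2-fold higher in the library labelled stress than in the one labelled release in 3 of 3 genotypes, and the dehydration medians, labelled stress over labelled release, were -2.82 in WT, -0.94 in aba2-1 and -2.201 in p5cs1-4. Both are consistent with the hypothesis that the labels of stress and release are exchanged in each genotype (the value of that test is 3 genotypes of 3), as are the endings of the names of the deposited tables. The test written before set no condition against the control. Exchanged labels would also lead to PRODH1 above the control in labelled stress, as the gene is known to be induced on release. It was not above it in WT (188 against 187 CPM). In aba2-1 it was 1.54-fold (1.45 to 1.63) higher and in p5cs1-4 1.93-fold (1.81 to 2.05) higher. In WT the PRODH1 difference thus rests on its low level in labelled release (25.5 CPM). Against the control, the dehydration median in labelled stress was -1.09 in WT, -1.07 in aba2-1 and 0.05 in p5cs1-4, the last within the random range. In labelled release it was 1.85, -0.30 (within that range) and 2.37. So the list stood above the random range in labelled stress in no genotype, which argues against correct labels for these genes. The aba2-1 labelled release value does not go with an exchange either. That seedlings released for 10 h carry more dehydration transcript and less PRODH1 than stressed seedlings was not tested apart from the labels. Beyond the values of this list it stays open. If the labels were exchanged, each direction given for labelled stress would hold for release, and the reverse.

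The aba2-1 control library correlated across genes at r = 0.968 with p5cs1-4 labelled stress, which stood closer to all 3 aba2-1 libraries (r = 0.968, 0.965 and 0.953) than to the other p5cs1-4 libraries (0.940 and 0.922). A close pair across genotype and treatment was not particular to them, as WT labelled stress and the p5cs1-4 control correlated at r = 0.969. Flavonoid medians above the WT control were 3.70 in the aba2-1 control, 2.69 in p5cs1-4 labelled stress, 2.46 in aba2-1 labelled stress and 2.55 in aba2-1 labelled release. They were also 4.13 in WT labelled release and 3.62 in p5cs1-4 labelled release, so a high flavonoid level does not mark the former libraries alone. RNA or reads carried over from WT labelled release into the aba2-1 control, as the only source of both lists at an equal share, were argued against. The share of the WT labelled release level was 7.90% (2.47 to 31.1) over 9 dehydration genes and 96.1% (29.2 to 156) over 11 flavonoid genes, a ratio of 12.2. A smaller carry-over beside another source of flavonoid transcript was not tested, nor was p5cs1-4 labelled release as a source. An exchange of the aba2-1 control with the p5cs1-4 labelled stress library cannot be told apart from correct labels by this test, because only 2 genes set the other p5cs1-4 libraries apart. AT5G11330 (protein-coding, chromosome 5, 3617138 to 3618913, minus strand, TAIR10.1, named here after its values were seen) stood near them in p5cs1-4 labelled stress (29.7 CPM against 25.5 and 26.2), and SRO5, whose reads are uncertain, did not (1 of 2). In the aba2-1 control neither gene stood near them (0 of 2), with AT5G11330 at 103.7 CPM and SRO5 at 5.585 CPM, against 20.51 and 25.61 CPM of SRO5 in the other p5cs1-4 libraries. SRO5 stood at 5.262 CPM in p5cs1-4 labelled stress as well, so it does not separate the libraries. The values of AT5G11330 go against an exchange, but that rests on this gene alone. Another genotype in the aba2-1 control cannot be told apart either, as 14 of 27 genes (51.9%) that set the other aba2-1 libraries apart stood nearer to them there, and 13 (48.1%) did so in p5cs1-4 labelled stress. An effect of the aba2-1 genotype on seedlings of the control plates stays open, untested.

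The log2 medians that follow had opposite signs in libraries or genotypes under the same contrast and lay outside the range of random lists. With 1 library per group the difference was not tested. The clade A phosphatase median was for aba2-1 against WT 0.52 in the control and -2.68 in labelled release. The ABA receptor median was for aba2-1 against WT -0.49 in labelled stress and 1.25 in labelled release. The dehydration median was for aba2-1 against WT 0.25 in the control and -2.11 in labelled release, and for p5cs1-4 against WT -0.27 in the control, 0.48 in labelled stress and 0.12 in labelled release. The aquaporin median was for aba2-1 against WT -0.81 in labelled stress and 0.21 in labelled release. The jasmonate median was for labelled release against the control -1.79 in WT, 0.21 in aba2-1 and -0.83 in p5cs1-4, and for aba2-1 against WT -1.48 in the control, 0.72 in labelled stress and 0.42 in labelled release. It was for p5cs1-4 against WT -0.41 in labelled stress and 1.07 in labelled release, and for labelled stress against the control -0.97 in WT, 1.09 in aba2-1 and -1.28 in p5cs1-4. It was for labelled release against labelled stress -0.79 in WT, -0.85 in aba2-1 and 0.74 in p5cs1-4.

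The same held for 4 further lists, for which the difference was not tested either. The salicylate median was for aba2-1 against WT 0.77 in labelled stress and -0.65 in labelled release, and for labelled stress against the control 0.81 in aba2-1 and -0.54 in p5cs1-4. The low-energy median was for aba2-1 against WT -0.52 in the control and 0.36 in labelled release, and for labelled stress against the control 0.48 in aba2-1 and -0.38 in p5cs1-4. The flavonoid median was for labelled release against the control 4.13 in WT, -1.62 in aba2-1 and 3.83 in p5cs1-4, and for aba2-1 against WT 3.70 in the control, 2.01 in labelled stress and -2.01 in labelled release. It was for p5cs1-4 against WT 2.83 in labelled stress and -0.44 in labelled release, and for labelled stress against the control -0.52 in WT, -1.74 in aba2-1 and 2.43 in p5cs1-4. The heat shock median was for labelled release against the control 1.38 in WT, -1.03 in aba2-1 and 0.80 in p5cs1-4, and for aba2-1 against WT 1.099 in the control, 0.69 in labelled stress and -1.51 in labelled release. It was for labelled release against labelled stress 1.31 in WT, -1.24 in aba2-1 and 0.92 in p5cs1-4.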

How the results depend on the processing

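The alternatives chosen after the data were seen were uniquely assigned reads, RPKM as deposited and the fit without the aba2-1 control library. No paired analysis was possible because each group is 1 library with no replicate numbers to pair, and the additive model instead compares treatments within the genotypes. C, S and R stand for control, labelled stress and labelled release, and a solidus for a ratio. For list medians the spread of random lists was the measure of a move. It covers variation between genes of the same libraries, not between replicates, and takes the members of a list as independent. No list median outside the range of random lists changed sign under another scaling. Counts of genes 2-fold apart stayed within 1.5 times of those reported for all 30 counts with a pseudocount of 0.1, with median-of-ratios scaling and with uniquely assigned reads. The additive counts did so for all 10 with median-of-ratios scaling, with no filter and with uniquely assigned reads. Median-of-ratios scaling moved the share of higher genes by up to 6.99 points and the median of all genes by up to 0.042, and RPKM moved that median by up to 0.194. Of the log2 ratios of single named genes and list members, 36 moved beyond their counting interval with a pseudocount of 0.1, 12 with median-of-ratios scaling and 15 with uniquely assigned reads, and none changed sign while past the 2-fold limit. Of the pairs of gene and contrast that the rule for named genes took from the additive model, 21 were on the same side of the threshold with DESeq2 and 29 passed it only there. In all that follows the cause was not tested.

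Without a floor the higher genes were 1342 (WT S/C), 1257 (aba2-1 R/C), 1160 (p5cs1-4/WT C) and 495 (p5cs1-4/WT R), and the lower genes 328 (p5cs1-4/WT R). With a floor of 20 CPM fewer genes could pass, and the higher genes were 154 (WT S/C), 1076 (WT R/C), 993 (WT R/S), 334 (aba2-1 S/C), 263 (aba2-1 R/C), 319 (aba2-1 R/S), 335 (p5cs1-4 S/C), 826 (p5cs1-4 R/C), 616 (p5cs1-4 R/S), 639 (aba2-1/WT C), 543 (aba2-1/WT S), 321 (aba2-1/WT R), 132 (p5cs1-4/WT C), 453 (p5cs1-4/WT S) and 76 (p5cs1-4/WT R). The lower genes were then 263 (WT S/C), 1231 (WT R/S), 638 (p5cs1-4 S/C), 673 (p5cs1-4 R/S), 931 (aba2-1/WT C), 174 (p5cs1-4/WT C), 696 (p5cs1-4/WT S) and 89 (p5cs1-4/WT R). With RPKM the lower genes were 593 (aba2-1 R/C), 617 (p5cs1-4 S/C) and 684 (aba2-1/WT S).

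With a pseudocount of 0.1, 36 list medians moved by more than that spread. The phosphatase median became -0.93 (WT S/C), -1.48 (aba2-1 S/C), 1.02 (aba2-1 R/S), 0.96 (aba2-1/WT C) and 1.45 (p5cs1-4/WT S). The dehydration median became -1.18 (WT S/C). The glucosinolate median became -1.43 (p5cs1-4 R/C). The cell wall median became -1.57 (WT R/S) and 1.17 (aba2-1/WT R). The flavonoid median became -1.05 (WT S/C), 4.90 (WT R/C), 5.10 (WT R/S), 3.27 (p5cs1-4 S/C), 4.198 (p5cs1-4 R/C), 4.95 (aba2-1/WT C), 2.51 (aba2-1/WT S) and 3.55 (p5cs1-4/WT S). The heat shock median became 2.45 (WT R/C), 2.09 (WT R/S), -1.38 (aba2-1 R/C), 1.64 (aba2-1/WT C), 1.54 (aba2-1/WT S) and -2.19 (aba2-1/WT R). The root marker median became 2.21 (p5cs1-4 S/C), 2.04 (aba2-1/WT C) and 3.05 (p5cs1-4/WT S). The seed marker median became -3.25 (WT S/C), 4.12 (WT R/C), 6.43 (WT R/S), -2.24 (aba2-1 S/C), 2.29 (aba2-1 R/S), 3.95 (p5cs1-4 R/C), 3.52 (p5cs1-4 R/S), -3.92 (aba2-1/WT R), -1.94 (p5cs1-4/WT C) and 2.17 (p5cs1-4/WT S).

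With uniquely assigned reads 14 list medians moved, and 5 of the 9 release markers, all bZIP genes, had no such reads. The release marker median became -0.74 (WT S/C), -2.29 (WT R/C), 0.95 (aba2-1 S/C), -0.78 (aba2-1 R/C), -2.07 (aba2-1 R/S), -0.12 (p5cs1-4 S/C), -1.33 (p5cs1-4 R/C), 0.10 (aba2-1/WT R) and 0.65 (p5cs1-4/WT R). The flavonoid median became -0.22 (WT S/C), 4.28 (WT R/S), 3.39 (p5cs1-4 R/C), 1.75 (aba2-1/WT S) and 2.66 (p5cs1-4/WT S). With RPKM, relative to the shift of all genes, 3 moved. The dehydration median became -1.001 (WT S/C). The flavonoid median became 1.83 (aba2-1/WT S) and 2.63 (p5cs1-4/WT S).

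In the additive model DESeq2 called 29 higher and 38 lower genes for S/C, 1292 and 1992 for R/C, 1120 and 1461 for R/S, 246 and 285 for aba2-1/WT and 81 and 76 for p5cs1-4/WT. Without the aba2-1 control library edgeR called 1242 and 1745 for R/C, 820 and 1035 for R/S and 1 lower gene for aba2-1/WT. With each genotype left out in turn the higher genes ran from 0 to 1524 for R/C and from 0 to 802 for R/S, and the lower genes from 0 to 2309 and from 0 to 1091. The values of 0 came without WT (3150 and 2969 genes at an unadjusted p under 0.05) and without p5cs1-4 (2345 and 2391), the highest without aba2-1. With a treatment left out edgeR called 0 genes for aba2-1/WT (2510, 851 and 3595 at an unadjusted p under 0.05 without control, labelled stress and labelled release) and 0 for p5cs1-4/WT (1895, 546 and 1953). Depth limits low genes most in the WT control, at 4898426 reads.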

Other observations

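The tests of other splits of the libraries were chosen after the result was seen. Single members of several lists, not yet described, also passed the additive test (edgeR, Benjamini-Hochberg adjustment, log2 fold ± SE). P5CS2, which encodes the second isoform of the enzyme of proline synthesis, rose by 1.31 ± 0.21 from control to labelled release (adjusted p = 0.0252) and by 1.38 ± 0.21 from labelled stress (adjusted p = 0.0295), and stood at 424 CPM in WT labelled release against 151 CPM in the WT control. BCAT2, of branched-chain amino acid metabolism, rose by 2.83 ± 0.49 from control to labelled release (adjusted p = 0.0281), and stood at 62.5 CPM in aba2-1 labelled stress against 15.1 CPM in WT labelled stress. FLS1, a flavonol synthase gene, rose by 1.93 ± 0.41 and CYP71A13, of camalexin synthesis, by 2.04 ± 0.44. The ABA receptor gene PYL1 fell by 1.15 ± 0.21 and PCNA1, of DNA replication, by 1.35 ± 0.28 in that contrast, with adjusted p between 0.0281 and 0.0452 for these 5. These genes were chosen after their values were seen.

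Markers of plant parts were measured in these libraries of whole seedlings, and a median given here need not lie outside the range of random lists. The photosynthesis genes had a median level of 2210.1 CPM in the WT control, 792 CPM in WT labelled release and 506 CPM in p5cs1-4 labelled release. It was 972 CPM in the aba2-1 control, 694 CPM in aba2-1 labelled stress, 844 CPM in aba2-1 labelled release and 866 CPM in p5cs1-4 labelled stress. The root markers had a median log2 ratio to the WT control of 2.32 in p5cs1-4 labelled stress, 1.22 in p5cs1-4 labelled release, 1.14 in the aba2-1 control, 1.09 in aba2-1 labelled stress and 1.01 in WT labelled release, the last within the range of random lists (-1.20 to 1.43). The seed markers, of which 3 were measured, had one of 2.70 in WT labelled release, also within the range of random lists of 3 genes (-2.26 to 2.70), and 2.37 in p5cs1-4 labelled release, and of -0.74 in aba2-1 labelled release.

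With 6 libraries in a contrast there are 10 splits into groups of 3, too few for a share under 0.05. Most of the splits also put both libraries of a genotype, or of a treatment in the genotype contrasts, on 1 side. In those the tested term overlaps with the other factor of the model, unlike in the real split, so the counts are a description only. For labelled release against control the real split called 1123 genes and the highest of the others 0 (1 of 10 splits had as many). For labelled release against labelled stress the values were 730 and 223 (1 of 10). For labelled stress against control the real split called 0 genes with edgeR (1617 at an unadjusted p under 0.05, 67 with DESeq2) and the highest other 501, with all 10 splits at least as large, and for p5cs1-4 against WT 0 (2107 and 157) and 1247, again all 10. For aba2-1 against WT the real split and the highest other called 0 (2875 at an unadjusted p under 0.05 and 531 with DESeq2 for the real one), so all 10 had as many. The split with 501 genes put the WT control, WT labelled stress and p5cs1-4 control libraries on 1 side, against the aba2-1 control, aba2-1 labelled stress and p5cs1-4 labelled stress libraries. The split with 1247 genes set the WT control, WT labelled stress and p5cs1-4 control libraries against WT labelled release, p5cs1-4 labelled stress and p5cs1-4 labelled release. Splits that call so many more genes than the real one point to a structure of the libraries other than the factor tested. The split with 501 genes set the WT against the aba2-1 libraries, with those of p5cs1-4 divided. The split with 1247 genes set the controls against the libraries labelled release, with those labelled stress divided. Beyond this overlap with the other factor, what that structure is was not tested.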
